A study of Homo sapiens with 19 samples.

How the data were processed

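Total RNA from U2OS cells infected with an adenovirus for HIC1 (Ad-HIC1) or for GFP (Ad-GFP) was labelled with biotin and hybridised to 1-colour arrays, per the labels. The deposited values are linear intensities, 1 for each of 22283 probe sets on each of 19 arrays, and the values themselves show that the authors scaled each array so that the mean intensity, without the lowest and highest 2%, is about 150. The software that made the intensities, and any background step, are not given in the sources used here. Arrays were grouped by virus and hour from their labels, which gave 9 Ad-HIC1 and 9 Ad-GFP arrays at the same 9 hours. The remaining array, whose title and description disagree, was left out of every comparison. No 2 arrays held identical values.

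Intensities were turned into log2(intensity + 16) and kept otherwise as deposited. Of the probe sets, 19071 carried 1 gene symbol, 1043 several and 2169 none. Of those with 1 symbol, 19059 were matched by gene identifier to the reference table of human gene names, and 0 symbols were replaced. Probe sets below the median of the mean log2 value (6.08, an intensity of 51.6) were dropped, which left 11142. For each gene with probe sets of 1 symbol, the brightest was used, which gave 6964 genes. No genome build was named for the probes, so no coordinates were used. Array signal has no sequencing depth, and the precision comes from the spread between arrays.

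Differences between the viruses were fitted with limma 3.58.1 (moderated t, with an intensity trend) with hour as a factor, and p-values were adjusted by Benjamini-Hochberg to a threshold of 0.05. The same was done for windows of 3 hours, with a common spread, for the interaction of virus and hour, and for the slope with hour in each group, with both groups in 1 fit. Slopes and interactions are given as the change over the 18 h from 8 to 26 h. The hours come from the labels and are part of the design. Arrays of the same hour deviated from their group means with correlations of -0.082 to 0.471. HIC1 and the array measures were tested by a two-sided exact sign-flip over the 9 matched hours, whose smallest p is 0.00391.

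In total 22 gene lists were written from general knowledge. They cover reported HIC1 targets, p53 targets, mitosis, DNA replication, interferon response, NF-kB, BCL2 family, Wnt targets, Eph receptors and ephrins, unfolded protein response, heat shock, hypoxia and glycolysis, cholesterol synthesis, immediate early, matrix and osteoblast, TGF-beta targets, circadian clock, ribosomal proteins, ribosome biogenesis, HIC1 corepressors, and epithelial and leukocyte markers. The 19 lists with at least 5 tested members were tested by the exact sign-flip on the mean difference relative to all genes at each hour. Their trends were tested by an exact permutation of the hours. Camera from limma was the alternative for this difference. Fry from limma was also run, which tests members against no change and not against all genes.

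Genes were named by a fixed rule, covering HIC1, the 12 largest increases and 12 largest decreases with 1 sign at 8 or more hours, the reported targets on the array, up to 4 members of each other list with the smallest p, the 5 largest positive and negative interactions, and the 8 largest rises and falls with hour in each group. Of these, 1 gene is not reported here. Another 20 genes were named after their values were seen, because a list had 5 or fewer calls in a direction.

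The comparisons, lists, naming rule and alternatives were fixed before the data were examined, except for the fit without the Ad-GFP 26 h array, which was added later. The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a stricter filter, the mean over probe sets, every probe set by itself, no _s_at or _x_at probe sets, no intensity trend, array weights, each hour left out, 8, 16 and 26 h left out together (hours that hold an array whose title carries another suffix), no hour term, a linear hour term and each group alone.

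The fits were tested on simulated data of 6964 genes with 50 changed genes at each size. At a log2 size of 0.5 the share recovered was 94% over all hours, 34%, 58% and 62% in the early, middle and late windows, 2% for the interaction, and 16% for each trend. At a size of 1 it was 100%, 98%, 100%, 100%, 56%, 94% (Ad-GFP) and 88% (Ad-HIC1). Each of these shares comes from 1 simulated data set per comparison. The 3 windows have the same design, so their unequal shares do not show unequal sensitivity. False calls were 10 over all hours and 3 to 8 elsewhere. A shift of 0.1 was recovered in 9% of simulated lists and one of 0.2 in 90%. Smaller changes were therefore often missed in the simulations. Far fewer genes changed there than were called in the data, and members of simulated lists were independent of each other. The shares recovered need not carry over to the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 were used.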

Results

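Transcript levels were measured in U2OS cells, an established human osteosarcoma line, after infection with an adenovirus that made the cells express either HIC1, a zinc-finger transcriptional repressor, or GFP, the green fluorescent protein that served as the control. Total RNA was taken 8, 12, 14, 16, 18, 20, 22, 24 and 26 h after infection and hybridised, labelled with biotin, to 1-colour arrays of 22283 probe sets. The Ad-HIC1 group had 9 arrays and the Ad-GFP group 9, with 1 array for each virus and hour. Another array carried labels that disagree about its treatment and entered no comparison. No hour had a replicate of its own, so the matched hours supplied the error of every virus comparison, and their number limits its precision. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

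The arrays were alike in scale, with medians of 48.1 to 61.8 after the deposited scaling. The Ad-GFP array of 26 h stood apart from the others. Its title also carries a suffix that no other array has, whose meaning was not established. Its spiked hybridisation controls averaged 1573, against 712 to 896 on the other 17 arrays compared, and its mean correlation with its own group, taken across probe sets, was 0.961. Between the groups, the array median was 54.6 ± 3.9 (SD, n = 9) with Ad-GFP and 50.9 ± 2.62 with Ad-HIC1 (two-sided exact sign-flip p = 0.0664, adjusted p = 0.133 over 4 measures). The ratio of 3' to 5' GAPDH signal, a sign of RNA integrity, was 0.880 ± 0.0508 and 0.841 ± 0.0361 (exact sign-flip p = 0.0508, adjusted p = 0.133). The first principal component held 47.2% of the variance of the tested genes and separated the viruses at every hour. The Ad-HIC1 score moved from -5.93 at 8 h to 23.6 at 26 h, whereas the Ad-GFP scores stayed between -17.8 and -10.7.

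**Figure D1:**
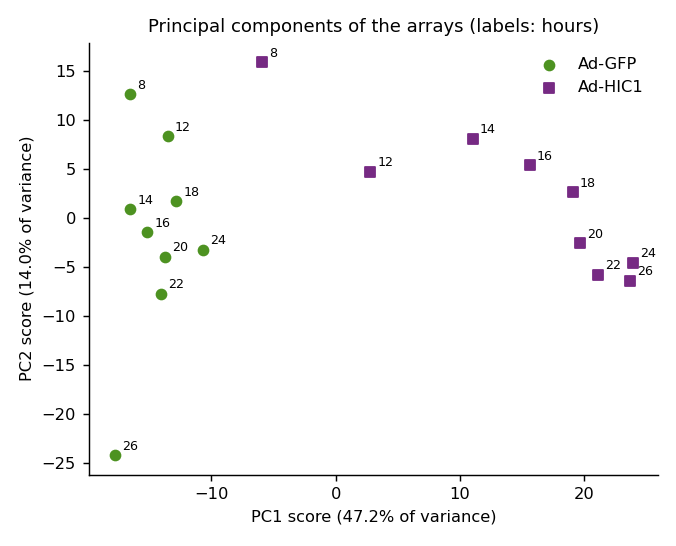
Scores of the 18 arrays on the first and second principal components of log2 intensity (47.2% and 14.0% of the variance), with circles for Ad-GFP, squares for Ad-HIC1 and the hour beside each point. The Ad-HIC1 arrays move along the first component from -5.93 at 8 h to 23.6 at 26 h, and the Ad-GFP 26 h array lies alone at -24.2 on the second.

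The HIC1 transcript level, from its only probe set, was read first, as a check of the labels. Its intensity lay between 0.834 and 7.68 on the Ad-GFP arrays, below the lower quartile of every array. With Ad-HIC1 it was already 1589 at 8 h, reached 3454 at 12 h and stood at 5816 at 26 h. The mean was 3 ± 2.35 (SD, n = 9) with Ad-GFP and 4196 ± 1373 with Ad-HIC1, and HIC1 was higher with Ad-HIC1 at 9 of 9 hours (two-sided exact sign-flip p = 0.00391, the smallest that 9 hours can give). The log2 difference was 7.71 ± 0.14 (SE) with a pseudocount of 16, 10.14 with 1 and 5.91 with 64, so that it shows direction and not a true fold. No Ad-HIC1 array lacked the transcript and no Ad-GFP array held it at a comparable level.

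**Figure D2:**
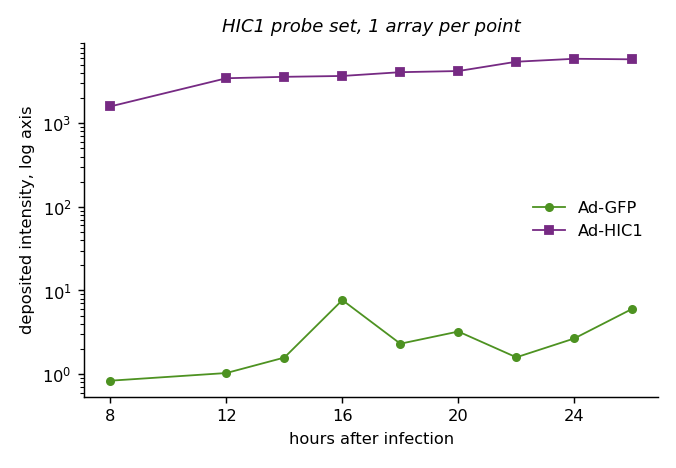
Deposited intensity of the HIC1 probe set (log axis) against hours after infection, 1 array per point, circles for Ad-GFP and squares for Ad-HIC1. The Ad-GFP arrays lie between 0.834 and 7.68 and the Ad-HIC1 arrays between 1589 and 5903.

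The stated purpose of the series was to find genes controlled by HIC1, which the comparison of the viruses over all hours addresses. The cells expressing HIC1 lost transcripts of SNAPC1, a subunit of the complex that drives small nuclear RNA genes, of TRIM16, of TNS3, a focal adhesion protein, of AMIGO2, an adhesion protein, and of ACKR3, an atypical chemokine receptor that binds CXCL12. SNAPC1 intensity was 1277 ± 177 (SD, n = 9) with Ad-GFP and 204 ± 129 with Ad-HIC1, a log2 difference of -2.68 ± 0.16 (SE). They gained ID4, an inhibitor of DNA binding by helix-loop-helix factors, from 115 ± 41.4 to 532 ± 89.4, and MMP12, the macrophage metalloelastase, from 45.2 ± 9.92 to 264 ± 124. Of 6964 genes tested with limma, 2935 differed after Benjamini-Hochberg adjustment, 1573 higher and 1362 lower with Ad-HIC1.

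Among the largest decreases, TRIM16 differed by -2.38 ± 0.18, TNS3 by -2.13 ± 0.16, AMIGO2 by -2.01 ± 0.16 and ACKR3 by -1.96 ± 0.13 on the log2 scale, each lower at 9 of 9 hours. LIF, a cytokine of the interleukin-6 family, was lower by a log2 difference of -1.74 ± 0.09 (adjusted p = 4.63e-09). The same direction at 9 of 9 hours was seen for AHNAK2 (-1.66), WDR6 (-1.62), SOX9 (-1.52), a transcription factor of the cartilage lineage, FHL2 (-1.47), a LIM-domain cofactor, ANO2 (-1.44), a calcium-activated chloride channel, and RIN2 (-1.42), an exchange factor for Rab GTPases. Among the largest increases, ID4 differed by 2.12 ± 0.16 and MMP12 by 2.03 ± 0.19. CA2, a carbonic anhydrase (1.78), SLC2A3, the glucose transporter GLUT3 (1.73), CDO1, the cysteine dioxygenase (1.67), PEAK1, a pseudokinase (1.62), PCDH7, a protocadherin (1.56), ABHD3 (1.56) and RBPMS, an RNA-binding protein (1.54), were each higher at 9 of 9 hours. The Ad-GFP means of MMP12, PEAK1 (24.7) and RBPMS (32.7) lay under the filter level of 51.6, and the pseudocount understates such changes.

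PTN, a heparin-binding growth factor, gave the second largest increase after HIC1, a log2 difference of 5.80 ± 0.19, but only on 1 of its 4 probe sets (27.9 ± 15.5 with Ad-GFP, 2393 ± 576 with Ad-HIC1). The other 3 PTN probe sets differed by 0.27, 0.65 and 0.90. Probe sets also disagreed in size for ID4 (0.37 and 0.53 on the other probe sets), PCDH7 (1.36, 0.48 and -0.03), RBPMS (2.04, 0.49 and -0.13) and SLC2A3 (0.65 and 1.02). The SLC2A3 intensity with Ad-GFP was 17.6, 12.8 and 18.4 at 8, 14 and 16 h, under the filter level, and its log2 difference went from 2.80 at 16 h to 0.29 at 24 h. The direction of all 24 genes with the largest differences was the same under each scaling tried. Centring each array on its median changed the split to 1990 higher and 883 lower. The total was 4533 of 11111 with each probe set tested by itself. It was 1767 of 4062 tested genes without probe sets whose names mark possible cross-hybridisation (_s_at, _x_at). These totals move with the number tested, which was 6964 in the main fit.

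Genes reported elsewhere as direct HIC1 targets were mostly lower with Ad-HIC1. Of the 9 tested, 6 were lower. ACKR3 and SOX9 are given above. CCND1, which encodes cyclin D1, went from 291 ± 40.1 (SD, n = 9) to 116 ± 53.3 (log2 -1.28 ± 0.10). EPHA2, a receptor tyrosine kinase for ephrins, differed by -1.15 ± 0.13, LRP8, the apolipoprotein E receptor of the low-density lipoprotein receptor family, by -1.10 ± 0.10, and its relative VLDLR by -0.31 ± 0.08 (adjusted p = 0.00699). SIRT1, a deacetylase and HIC1 partner, was higher (0.47 ± 0.10, 9 of 9 hours, adjusted p = 0.00169). CDKN1A, the p21 cell cycle inhibitor (0.11 ± 0.09, adjusted p = 0.363), and CDKN1C, the p57 inhibitor (0.07 ± 0.11, adjusted p = 0.62), did not pass.

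The 9 as a group lay below all genes (mean log2 -0.75, SD 0.11 over 9 hours, lower at 9 of 9, exact sign-flip p = 0.00391, adjusted p = 0.0186, and adjusted p = 0.141 with an estimated correlation). Adjusted over the list alone, 6 were lower and 1 higher. Part of this list may have been chosen by its authors on these very arrays, so its direction is not independent evidence. The VLDLR call ended with median centring (adjusted p = 0.0516) and without the hour term (adjusted p = 0.0662). ATOH1 (0.03 ± 0.09), FGFBP1 (-0.63 ± 0.22), EFNA1 (-0.33 ± 0.16) and LCN2 (0.04 ± 0.13) lay below the intensity filter. Without that filter FGFBP1, a carrier protein for fibroblast growth factors, had an adjusted p of 0.0477 and the others of 0.133 or more.

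**Figure D3:**
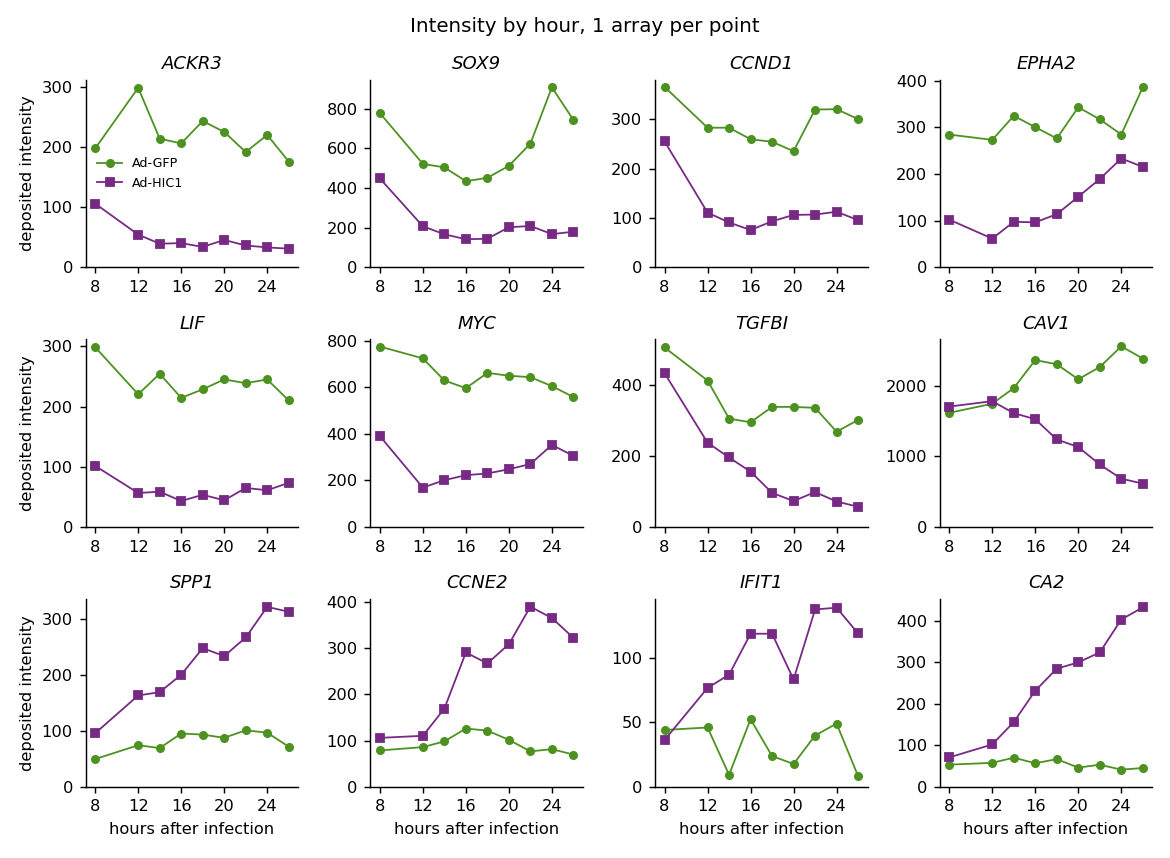
Deposited intensity of 12 named genes against hours after infection, 1 array per point, circles for Ad-GFP and squares for Ad-HIC1, each panel with its own axis from 0. ACKR3, SOX9, CCND1, LIF and MYC are lower with Ad-HIC1 at all 9 hours, EPHA2 approaches the Ad-GFP level late, and CCNE2, SPP1 and CA2 separate upward with time.

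The DNA replication and mitosis lists, fixed beforehand as all lists here, had positive means with Ad-HIC1, while most of their members did not pass. DNA replication genes lay 0.15 log2 units above all genes (SD 0.09 over 9 hours, higher at 9 of 9, exact sign-flip p = 0.00391, adjusted p = 0.0186, and adjusted p = 0.785 with an estimated correlation). Of the 26 tested, 9 were higher and 3 lower, with the same counts when adjusted over the list alone. CCNE2, a cyclin of S phase entry (93.2 ± 20 to 258 ± 106, log2 1.23), CDT1, a replication licensing factor (0.71), SLBP, which binds histone mRNA (0.41), and PCNA, the polymerase clamp (0.43), were higher at 9 of 9 hours. The 3 lower members were MCM3 (-0.25), RRM2 (-0.17) and RFC3 (-0.16). The other probe sets of RRM2 (-0.03) and RFC3 (0.05) did not pass, averaging probe sets ended both calls (adjusted p = 0.145 and 0.502), and RRM2 did not pass without _s_at and _x_at probe sets (0.761). Mitosis genes lay 0.11 above all genes (SD 0.10, 7 of 9 hours, exact sign-flip p = 0.0234, adjusted p = 0.0445, and adjusted p = 0.804 with an estimated correlation), with 9 of 27 higher and 2 lower (10 and 2 adjusted over the list alone). DLGAP5 (0.47), HMMR (0.41), both spindle proteins, and UBE2C (0.29), a ubiquitin-conjugating enzyme of mitotic exit, were higher, while the kinetochore protein CENPF (-0.42) and the phosphatase CDC25C (-0.27) were lower. The mitosis list did not pass after quantile normalization (adjusted p = 0.0742) or without any 1 of 7 of the hours (up to 0.0891). Leaving out 1 hour also ended the call of RFC3 for 6 hours (adjusted p up to 0.104) and of CDC25C for 4 (up to 0.0568), and median centring ended those of MCM3, RRM2, RFC3 and CDC25C (0.0959, 0.25, 0.359 and 0.127).

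The ribosome biogenesis and TGF-beta lists had negative means. Ribosome biogenesis genes lay below all genes (mean log2 -0.25, SD 0.14 over 9 hours, 8 of 9 hours, exact sign-flip p = 0.00781, adjusted p = 0.0212, and adjusted p = 0.662 with an estimated correlation), with 8 of 15 lower and 0 higher (9 and 0 adjusted over the list alone). RRS1 (-0.65), MYBBP1A (-0.62), NOP16 (-0.53) and WDR12 (-0.31), all nucleolar, were lower, as was MYC (-1.28), the transcription factor that drives many such genes, from 649 ± 66.1 to 266 ± 72.1. The 19 ribosomal protein genes did not move as a group (mean 0.03, exact sign-flip p = 0.387, adjusted p = 0.49), with RPS9 (0.39) and RPL30 (0.25) higher, RPL8 (0.11, adjusted p = 0.0711) and RPL3 (0.13, adjusted p = 0.0984) short of the threshold, and 0 lower. For RPS9 the other probe set gave 0.01, and RPL8 and RPL3 passed with median centring (adjusted p = 0.0069 and 0.013). TGF-beta target genes had a mean of -0.33 (SD 0.09, lower at 9 of 9 hours, exact sign-flip p = 0.00391, adjusted p = 0.0186, and adjusted p = 0.432 with an estimated correlation). Of 12 tested, 5 were lower, and the count adjusted over the list alone was the same. They were TGFBI, an extracellular matrix protein (-1.28), TIMP3, a metalloproteinase inhibitor (-1.05), SNAI2, a repressor of E-cadherin (-0.96), PMEPA1 (-0.96), which dampens SMAD signalling, and LTBP2 (-0.47), with ID3 (0.72), also a target of BMP signalling, and SKIL (0.34), a SMAD corepressor, higher.

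Immediate early genes had a mean of -0.19 (SD 0.18, lower at 8 of 9 hours, exact sign-flip p = 0.0117, adjusted p = 0.0247, and adjusted p = 0.804 with an estimated correlation). Of 10 tested, 5 were lower and 2 higher, also when adjusted over the list alone. The phosphatase DUSP1 (592 ± 91.2 to 311 ± 35.3, log2 -0.89), MYC, the matricellular CCN1 (-0.44), JUN (-0.30) and FOSL1 (-0.45), both AP-1 subunits, were lower. EGR1, a zinc-finger factor (0.93), and ATF3 (0.53) were higher. Without the intensity filter the list mean turned to 0.06 and did not pass (adjusted p = 0.397), and the JUN call ended with median centring (adjusted p = 0.0653). Eph receptor and ephrin genes had a mean of -0.19 (SD 0.15, 8 of 9 hours, exact sign-flip p = 0.0117, adjusted p = 0.0247, and adjusted p = 0.899 with an estimated correlation). In the 7 tested, the receptors EPHA2 and EPHB4 (-0.37) were lower and the ligands EFNA4 (0.33) and EFNA3 (0.34) higher (3 lower and 2 higher adjusted over the list alone). EPHA2 (-1.15) differed most among those named and weighs heavily in a mean of 7. It is also a reported HIC1 target, so this list is not independent of that one. The median over members was -0.22. The EFNA3 call ended without 18, 20 or 24 h (adjusted p up to 0.055). Of the 4 Wnt target genes tested, too few for a list test, CCND1 and MYC were lower, also when adjusted over the list alone, and BMP4 (-0.33, adjusted p = 0.119) and LEF1 (0.21, adjusted p = 0.198) did not pass. BMP4 passed with array weights (adjusted p = 0.0362) and without 12 h (0.0399) or 14 h (0.0495).

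The unfolded protein response, cholesterol synthesis and interferon lists had small positive means, while most of their members did not pass. The unfolded protein response list had a mean of 0.06 (SD 0.03, higher at 9 of 9 hours, exact sign-flip p = 0.00391, adjusted p = 0.0186, and adjusted p = 0.785 with an estimated correlation). Of 19 tested, 7 were higher and 1 lower, with the same counts adjusted over the list alone. DNAJB9 (0.72), a chaperone of the endoplasmic reticulum, ATF3 (0.53) and EDEM1 (0.39), of the degradation of misfolded proteins, were higher, and CHAC1, a glutathione-degrading enzyme, was lower (204 ± 26 to 80.3 ± 15.7, log2 -1.20). Cholesterol synthesis genes had a mean of 0.08 (SD 0.06, 8 of 9 hours, exact sign-flip p = 0.00781, adjusted p = 0.0212, and adjusted p = 0.899 with an estimated correlation). SC5D (0.52), MSMO1 (0.43), ACAT2 (0.23) and INSIG1 (0.23) made up the 4 higher of 13 tested, and 0 were lower (3 and 0 adjusted over the list alone). INSIG1, which retains the sterol sensor SCAP, lost its call without any 1 of 8 of the hours (adjusted p up to 0.11), without the hour term (0.363), without the filter (0.0772) and with a pseudocount of 64 (0.0505), whereas the other 2 INSIG1 probe sets gave 0.58 and 0.42 (adjusted p = 0.00191 and 0.0109). Interferon response genes had a mean of 0.16 (SD 0.12, 8 of 9 hours, exact sign-flip p = 0.00781, adjusted p = 0.0212, and adjusted p = 0.953 with an estimated correlation). Of 9 tested, the antiviral genes IFIT1 (1.32) and OAS3 (0.70) were higher and IFI44 (-0.59) lower, also when adjusted over the list alone, and IRF9 did not pass (0.28, adjusted p = 0.0648). The median over members was 0.07, and IFIT1, the largest of them, lay under the filter level on average with Ad-GFP. IRF9 passed without 8 h (0.0364) or 26 h (0.0201), with median centring (0.0255) and with weighted arrays (0.00468).

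The other lists did not pass as groups, with members moving in both directions. Matrix and osteoblast genes (mean 0.06, exact sign-flip p = 0.0586, adjusted p = 0.101) had 3 of 11 higher, SPP1, which encodes osteopontin (82 ± 16.9 to 223 ± 73.8, log2 1.24), COL3A1 (1.19) and the crosslinking enzyme LOX (0.53), and 4 lower, THBS1 (-0.71), COL1A1 (-0.47), COL6A3 (-0.38) and TNC (-0.31). The other COL3A1 probe sets gave 1.14, 0.70 and -0.25. The list passed without 24 h (adjusted p = 0.0445), and the calls of COL6A3 (0.112) and TNC (0.247) ended without the hour term, that of TNC also with median centring (0.088). NF-kB genes (mean -0.07, exact sign-flip p = 0.164, adjusted p = 0.24) had LIF and IER3 (-0.57) lower and NFKBIA, the NF-kB inhibitor (0.98), RELB (0.53), TNFAIP3 (0.43) and NFKB1 (0.38) higher of 9 tested (3 lower and 4 higher adjusted over the list alone), and without the filter the mean was 0.15 (adjusted p = 0.0107). Hypoxia and glycolysis genes (mean 0.04, exact sign-flip p = 0.207, adjusted p = 0.281) had NDRG1 (0.70), PFKFB3 (0.51), P4HA1 (0.33), BNIP3 (0.32) and KDM3A (0.27) higher (P4HA1 not without the hour term, adjusted p = 0.0632) and the hexokinase HK2 (-0.78) and glucose transporter SLC2A1 (-0.47) lower of 13. Circadian genes (mean 0.04, exact sign-flip p = 0.484, adjusted p = 0.575) had PER2 (0.58) and NFIL3 (0.44) higher and CRY1 (-0.57) and BHLHE41 (-0.42) lower of 9 (3 higher and 2 lower adjusted over the list alone). Heat shock genes (mean -0.05, exact sign-flip p = 0.0977, adjusted p = 0.155) had the small chaperone CRYAB (-1.39) lower and HSPH1 (0.35) and DNAJA1 (0.28) higher of 9, while HSPB1 differed by 0.17 (adjusted p = 0.0591). The heat shock list passed with quantile normalization and without 22 h (adjusted p = 0.0297 for each), HSPB1 passed without 8, 12 or 26 h (as low as 0.0202), and DNAJA1 did not without _s_at and _x_at probe sets (0.382).

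Targets of p53 had a mean near 0 over all hours (-0.002, exact sign-flip p = 0.965, adjusted p = 0.965). Members past the threshold were 2 lower and 0 higher early, 3 lower and 1 higher in the middle, and 6 higher and 0 lower late. The list itself was not tested by window. Of 16 tested, TIGAR (0.39), PPM1D (0.36), TP53I3 (0.23) and BAX (0.20) were higher and DDB2 (-0.37), FAS (-0.36) and PHLDA3 (-0.31) lower. BCL2 family genes (mean 0.006, exact sign-flip p = 0.809, adjusted p = 0.854) had MCL1 (0.36), PMAIP1 (0.36) and BAX higher and BCL2L2 (-0.24) lower of 8, although 1 other MCL1 probe set differed by -0.28. HIC1 corepressor genes (mean 0.007, exact sign-flip p = 0.73, adjusted p = 0.816) had SIRT1 and the deacetylase HDAC2 (0.29) higher and CTBP2 (-0.27), the chromatin remodellers ARID1A (-0.19) and CHD4 (-0.21) lower of 9. The other ARID1A probe sets gave -0.04, -0.09 and -0.33, none past the threshold. For CTBP2, 1 other probe set gave 0.04, while the rest were lower. Counts adjusted over the list alone were the same for the p53, BCL2 family, corepressor, matrix, hypoxia and heat shock lists. With 1 hour left out, calls ended for CHD4 (7 of 9 hours, adjusted p up to 0.103), HDAC2 (4, up to 0.0628), PMAIP1 (4, up to 0.0675), BCL2L2 (3, up to 0.0829) and BAX (1, 20 h, 0.0631). Median centring ended those of ARID1A, CHD4 and BCL2L2 (adjusted p = 0.147, 0.166 and 0.16), averaging probe sets ended that of BAX (0.0933), and leaving out the hour term ended that of DDB2 (0.131). Without the filter the BCL2 family list had a mean of 0.12 and passed (adjusted p = 0.043). Of 13 epithelial markers 3 were tested and of 12 leukocyte markers also 3. The junction protein OCLN was higher (0.68), while KRT8 (0.11, adjusted p = 0.164) and KRT18 (-0.05, adjusted p = 0.485) did not pass. With median centring KRT8 had an adjusted p of 0.0472, and the log2 difference of KRT18 turned to 0.02. LCP1 was higher (0.70) and ITGB2 lower (-0.38). CD48 did not pass (-0.02, adjusted p = 0.904), and its log2 difference turned to 0.06 with median centring. Counts adjusted over each list alone were the same.

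In all, 10 of the 19 lists with at least 5 tested members passed, 5 higher and 5 lower. None of these calls held in limma's camera test with an estimated correlation (0 of 19 lists, lowest adjusted p = 0.141 for the reported targets). With the preset correlation of 0.01, 2 held, the reported targets (adjusted p = 0.0117) and ribosome biogenesis (adjusted p = 0.0163). The fry test asks another question, whether members differ from no change and not from all genes, and there 9 lists passed. Interferon response (fry adjusted p = 0.207) and Eph and ephrin genes (0.0563) were not among them. The NF-kB list, which had not passed the sign-flip test, was among them (lower, fry adjusted p = 0.035). It held 4 genes higher and 2 lower of 9 tested. LIF (-1.74) differed most among those named and weighs heavily in its direction. The mean relative to all genes and the median of the members differed in sign for the matrix, heat shock, BCL2, circadian and p53 lists, and camera gave the other direction from the mean for the matrix, heat shock, p53 and corepressor lists. In total 20 of the genes named in the list paragraphs fall outside the naming rule and were chosen after their values were seen, since a list had 5 or fewer calls in that direction.

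**Figure D4:**
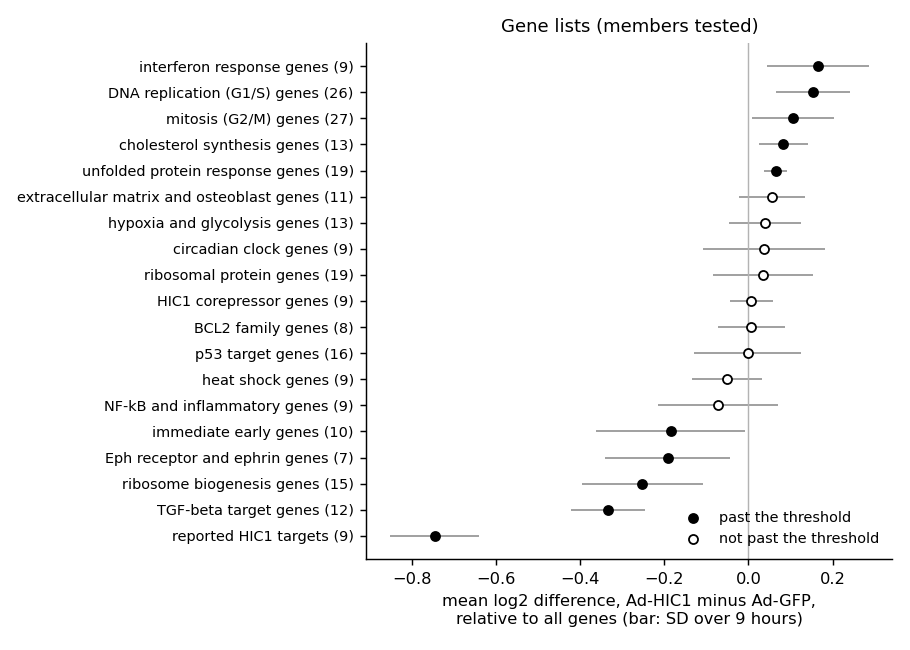
Mean log2 difference (Ad-HIC1 minus Ad-GFP) of each of the 19 gene lists relative to all genes, with bars for the SD over the 9 matched hours and the number of tested members in parentheses. Filled points passed the exact sign-flip test after adjustment, from -0.75 for the reported HIC1 targets to 0.16 for interferon response genes.

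The next comparison asked how early the difference appeared, in windows of 3 hours each. The HIC1 transcript also rose with hour under Ad-HIC1, so the windows differ in HIC1 level as well as in time. In the early window (8, 12 and 14 h), LIF (log2 -1.66), ACKR3 (-1.68), EPHA2 (-1.61), RIN2 (-1.60), MYC (-1.51), SOX9 (-1.19) and CCND1 (-1.07) were already lower. In the early window 6 of the 9 reported targets were lower and 0 higher, with VLDLR at -0.54 (adjusted p = 0.0225), whereas VLDLR did not pass in the middle (-0.23, adjusted p = 0.19) or late window (-0.17, adjusted p = 0.32), a change that was itself not past the threshold (adjusted p = 0.11). The number of genes that differed was 382 early (158 higher, 224 lower), 1650 in the middle window of 16, 18 and 20 h (877 higher, 773 lower) and 2409 in the late window of 22, 24 and 26 h (1335 higher, 1074 lower). Of the 158 genes higher early, 127 were also higher late, against 30.3 if the lists were independent. Of the 224 lower early, 154 were also lower late, against 34.6. The windows share a common spread, so the counts under independence are no strict baseline.

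Each window rests on 3 pairs of arrays. The early count was 182 without 12 h and 123 without 14 h, and the middle count 917, 848 and 807 without 16, 18 or 20 h. Median centring gave 223 genes early, a split of 965 higher and 469 lower in the middle window and of 1585 higher and 599 lower in the late one. Without _s_at and _x_at probe sets, when 4062 genes were tested, the counts were 236, 996 and 1428. Dropping 8, 16 and 26 h together left 1034 in the middle and 1376 in the late window, array weights gave 2685 in the middle window, and testing each probe set by itself gave 3662 in the late one.

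Whether the difference between the viruses grew or shrank with time was tested as an interaction of virus and hour. It is given as the change of the log2 difference from 8 to 26 h. The HIC1 transcript itself rose with Ad-HIC1, from 1589 at 8 h to 5816 at 26 h (interaction change 1.39, limma adjusted p = 0.00713). Time after infection and HIC1 level therefore cannot be told apart. The difference widened upward for CA2, from 0.32 at 8 h to 2.87 at 26 h (change 2.80 ± 0.24 SE, n = 9 hours, adjusted p = 2.45e-05), and for AOPEP, an aminopeptidase (2.66 ± 0.28), SNX10, a sorting nexin (2.64 ± 0.38), and BBOF1 (2.53 ± 0.27). HP1BP3, a heterochromatin protein, changed most (3.19 ± 0.56), from -1.34 at 8 h to 2.06 at 26 h. Both ends rest on an intensity under the filter level of 51.6, namely 24.7 with Ad-HIC1 at 8 h and 22.7 with Ad-GFP at 26 h. With Ad-GFP, HP1BP3 went from 92.8 at 12 h to 21.25 at 14 h. AOPEP lay between 20.1 and 35.5 on the Ad-GFP arrays, also under that level. The difference widened downward for CAV1, the main protein of caveolae, from 0.08 at 8 h to -1.93 at 26 h (-2.23 ± 0.19), and for MN1 (-1.94 ± 0.21), CRYAB (-1.93 ± 0.20), TGFBI (-1.91 ± 0.27) and MICAL2, an actin-oxidising enzyme (-1.92 ± 0.18). In total 574 genes passed, 374 with a positive and 200 with a negative change.

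Of the 374, 269 were also higher over all hours, against 84.5 if the lists were independent, and of the 200, 143 were also lower, against 39.1. Both lists use the same arrays, and a difference that widens from near 0 also moves the mean over all hours. The counts under independence are therefore no baseline. A shrinking decrease was rarer, with 8 genes lower over all hours and a positive change, among them EPHA2 (-1.61 early, -0.59 late, change 1.24 ± 0.29), EPHB4 (0.75) and FOSL1 (1.26). CDKN1A, which did not pass over all hours, had a change of 0.85 ± 0.20 (adjusted p = 0.0176). The count was 237 without 8 h, 345 without 12 h and 344 without 26 h (188 positive, 156 negative), and HP1BP3 did not pass without 8 h (2.60, adjusted p = 0.0586). It was 345 without the Ad-GFP 26 h array alone (190 positive, 155 negative). With hour as a factor, an array without its pair adds nothing to the interaction, so this fit repeats that without 26 h. Most of the excess of positive changes thus went with the 26 h pair. Neither array of the pair, nor a change at the last hour, can be singled out. The count was 63 without 8, 16 and 26 h, when HP1BP3 and TGFBI did not pass (adjusted p = 0.188 and 0.106). It was 379 without the filter, 314 without _s_at and _x_at probe sets, and 417 (319 positive, 98 negative) with median centring.

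Changes with time under the control virus were taken from the Ad-GFP arrays, as fitted log2 changes over the 18 h from 8 to 26 h. SLC2A3 rose most (2.60 ± 0.45 SE, n = 9 arrays), followed by BMP4, a bone morphogenetic protein (1.93 ± 0.24), ASCC1 (1.63), IGKC, annotated as an immunoglobulin light chain (1.61), PLAC8 (1.52), LAMA5, a laminin chain (1.42), HAPLN1, a link protein of cartilage matrix (1.40), and DDIT4, an inhibitor of mTORC1 signalling (1.33). PDLIM5, a PDZ and LIM domain protein (-2.44 ± 0.32), CORO2B, a coronin (-2.34 ± 0.19), GLIPR1 (-2.10), SYNE1, a nuclear envelope spectrin-repeat protein (-1.82), FLRT2 (-1.61), TBX3, a T-box repressor (-1.57), IL4R, the interleukin-4 receptor (-1.54), and BIRC2, an inhibitor of apoptosis (-1.53), fell. In all, 856 genes changed, 397 up and 459 down. For PDLIM5, FLRT2, IGKC, SYNE1, GLIPR1 and SLC2A3 some other probe sets of the gene gave smaller differences between the viruses over all hours. For PDLIM5 (0.85 against 0.56) and GLIPR1 (0.68 against 0.57) another probe set gave a larger one. The trends of these other probe sets with hour were not compared. The Ad-GFP 26 h array, the one that stood apart in its hybridisation controls, is the last point of this trend. Without it 481 genes passed, 363 of them among the 856, and ASCC1 (1.56, adjusted p = 0.0744), IGKC (1.23, 0.204) and TBX3 (-0.81, 0.124) did not. The count was 497 without the 26 h pair, 375 without 8 h, 51 without 8, 16 and 26 h, 495 from the Ad-GFP arrays alone, 460 without _s_at and _x_at probe sets, 1322 with each probe set by itself and 701 (159 up, 542 down) with median centring. Without 8 h ASCC1 (adjusted p = 0.0565), IGKC (0.266) and TBX3 (0.0717) did not pass, nor did IGKC without 20 h (0.0531). Without 8, 16 and 26 h these 3 and SLC2A3 (2.47, adjusted p = 0.143), HAPLN1 (0.0701), PDLIM5 (0.0578), SYNE1 (0.0539), FLRT2 (0.144) and IL4R (0.383) did not pass.

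Under Ad-HIC1, ALOX5, the 5-lipoxygenase that starts leukotriene synthesis, rose most (2.69 ± 0.19 SE, n = 9 arrays), with MMP12 (2.47), AOPEP (2.46), CA2 (2.45), BBOF1 (2.35), SNX10 (2.28), DBNDD1 (2.14) and CXADR, the receptor for coxsackievirus and adenovirus (2.12). TGM2, a transglutaminase (-3.07 ± 0.19), TGFBI (-2.54), SCG5, a neuroendocrine chaperone (-2.39), MICAL2 (-2.10), NAT10, an RNA acetyltransferase (-1.99), FGF1, a fibroblast growth factor (-1.93), LAMB3, a laminin chain (-1.85), and TBX3 (-1.83) fell. In all, 1890 genes changed, 1037 up and 853 down. Of the genes rising with Ad-GFP 158 also rose with Ad-HIC1, against 59.1 if the lists were independent, and of those falling 189 also fell, against 56.2. Both trends come from 1 fit with a common spread, so the counts under independence are no strict baseline. SCG5 (-1.51), FGF1 (-1.17) and TGM2 (-1.17) fell with Ad-GFP too, and ALOX5 rose (0.84). The change with hour differed between the viruses for TGM2, ALOX5, SCG5 and CXADR (interaction adjusted p = 0.000579, 0.000608, 0.0459 and 0.00286) but not past the threshold for FGF1 (0.236), DBNDD1 (0.0537) or TBX3 (0.789). For ALOX5, FGF1, TGM2 and MICAL2 some other probe sets showed smaller differences between the viruses over all hours, and their trends with hour were not compared. The count was 1088 without 8 h, 879 without 8, 16 and 26 h, 1103 without _s_at and _x_at probe sets and 2992 with each probe set by itself.

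The gene lists were followed with hour in each group, relative to all genes, and 21 of the 38 trends passed an exact permutation of the hours after adjustment. Cholesterol synthesis genes rose with either virus (0.30 with Ad-GFP and 0.30 with Ad-HIC1 on the log2 scale from 8 to 26 h, exact permutation p = 0.00137 and 0.0031, adjusted p = 0.00577 and 0.0101). The same was true of hypoxia and glycolysis genes (0.21 and 0.32), the unfolded protein response (0.15 and 0.16) and ribosomal protein genes (0.32 and 0.14). TGF-beta target genes (-0.34 and -0.48) and ribosome biogenesis genes (-0.18 and -0.44) fell with either. With Ad-HIC1, targets of p53 (0.41, exact permutation p = 0.000441, adjusted p = 0.00279), interferon response genes (0.36), Eph and ephrin genes (0.36) and DNA replication genes (0.31) rose, and matrix genes (-0.23) and corepressor genes (-0.09) fell. Their Ad-GFP trends were 0.10, 0.06, 0.17, 0.10, -0.11 and -0.05 and did not pass. With Ad-GFP, immediate early genes fell (-0.31, exact permutation p = 0.000896, adjusted p = 0.00425), and mitosis genes (0.21) and reported HIC1 targets (0.20) rose, while their Ad-HIC1 trends of 0.18, 0.15 and 0.12 did not pass. All Ad-GFP list trends end at the 26 h array that stood apart, and none was tested without it. The reported targets and the hypoxia list were near the threshold with Ad-GFP (exact permutation p = 0.0208 and 0.0219, adjusted p = 0.0396 for each). Whether a list's trend differed between the viruses was not tested. Trends of the NF-kB (-0.20 and 0.07), BCL2 (-0.13 and 0.07), heat shock (-0.003 and 0.06) and circadian lists (0.05 and 0.32) did not pass with either virus.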

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

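The tests of the PTN probe set and the counts from other assignments of the arrays were chosen after the results were seen, and the test of the Ad-GFP 26 h array was set before its result.

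The PTN increase rests on 1 of its 4 probe sets, with a log2 difference of 5.80. The largest difference of the other 3 PTN probe sets, 0.899, argues against an equal rise of the whole PTN mRNA, although this disagreement is what drew attention to the probe set. Over the Ad-HIC1 arrays the log2 ratio of this probe set to the HIC1 probe set had an SD of 0.173. Of the 1571 other genes higher with Ad-HIC1, 6 (0.382%) had a smaller one. A transcript of the cells that rose in step with HIC1 would also give a small SD. This measure therefore cannot separate such a rise from RNA made from the virus. The probe set may read viral RNA, although no probe or virus sequence was checked. A smaller rise of PTN itself stays open.

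The trends with hour under Ad-GFP end at the 26 h array, whose hybridisation controls (1573) and mean correlation with its group (0.961) were far from those of the other arrays. Of the 481 genes with a trend in the fit without this array, 74.2% (357) had a 26 h value on the side of the trend. Under 60% would point to the quality of that array alone and over 75% against it. The result lies between, so quality and a change with hour cannot be told apart with 1 array at 26 h.

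Other assignments of the viruses or hours to the same arrays gave fewer genes in each case. Exchanging the viruses within hours gave as many as the 2935 genes over all hours in 1 of 100 assignments, the real one, with 0 genes in each of the others. Reordering the hours did so in 1 of 100 for the 574 genes of the interaction (at most 82 otherwise), for the 856 genes of the Ad-GFP trend (at most 418) and for the 1890 genes of the Ad-HIC1 trend (at most 1447). Exchanging the viruses moves any real difference into the spread, so few genes in the other assignments were near fixed in advance. Hours from 1 culture would not be exchangeable, and the labels do not say that cultures were separate. The shares therefore describe these arrays only and do not exclude chance. For the windows there are only 4 assignments, too few for a share under 0.05, with 382 genes early, 1650 in the middle and 2409 late against at most 1, 0 and 0.

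Of 323 groups of 9 values 42 held an array far from the rest of its group by Dixon's test, where chance gives about 1 in 20, or 16.1. The 9 values come from different hours and the genes were named for their differences or trends. The first hour of a change can therefore stand out, and 16.1 is no baseline for these values. The Ad-HIC1 8 h array is also the only Ad-HIC1 array whose title carries another suffix. Its mean correlation with its own group, 0.972, was the lowest of the Ad-HIC1 arrays. A property of that array and the first hour cannot be told apart. Besides the controls and correlation above, the 3' to 5' ratio of ACTB was 1.28 on the Ad-HIC1 26 h array. The log2 values far from the group were, on Ad-HIC1 8 h, PTN 10.06, RBPMS 6.03, SNAPC1 9.13, TNS3 8.07, AMIGO2 9.82, ACKR3 6.93, SOX9 8.86, FHL2 9.55, CCND1 8.08, DLGAP5 9.31, HMMR 8.52, IFIT1 5.71, HK2 6.79, CCN1 10.23, NFIL3 7.33, RRS1 9.14, BIRC2 9.11 and TNFAIP3 7.79, and on Ad-GFP 8 h, PCDH7 7.71, CENPF 9.32, SLBP 8.35, LEF1 7.95, ATF3 7.23, MICAL2 10.36, SCG5 8.14 and LAMB3 9.003, and on Ad-HIC1 12 h, PCDH7 7.56, DDIT4 7.83, RRM2 10.96 and ID3 8.01, and on Ad-GFP 26 h, SIRT1 6.85, PHLDA3 8.73, UBE2C 10.93 and TBX3 4.65, and on Ad-HIC1 26 h, MSMO1 9.03, and on Ad-GFP 24 h, ACAT2 8.04 and PMEPA1 5.04, and on Ad-GFP 12 h, RPS9 10.04, and on Ad-HIC1 18 h, HAPLN1 6.96.

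The difference between the viruses changed with hour, by the test of the interaction, for 574 genes. It can change through either group. From 8 to 26 h PDLIM5 went from 482 to 33.2 with Ad-GFP and from 329 to 221 with Ad-HIC1. CA2 went from 53.4 to 45.2 with Ad-GFP and from 70.85 to 432.6 with Ad-HIC1. Changes with Ad-GFP end at the 26 h array that stood apart. HIC1, listed here too, is the gene carried by the virus. Among named genes the change of the log2 difference from 8 to 26 h was positive for HIC1 1.39, ID4 1.84, MMP12 2.05, CA2 2.80, PEAK1 1.52, PCDH7 1.43, EPHA2 1.24, CDKN1A 0.85, CCNE2 2.03, IFIT1 1.79, OAS3 1.26, NFKBIA 1.64, PMAIP1 1.15, LEF1 1.33, EPHB4 0.75, DNAJB9 0.93, ATF3 0.89, NDRG1 1.51, EGR1 1.25, SPP1 0.97, NFIL3 1.26, LCP1 1.18, HP1BP3 3.19, AOPEP 2.66, SNX10 2.64, BBOF1 2.53, PDLIM5 2.26, CORO2B 0.96, GLIPR1 1.37, IL4R 2.05, BIRC2 0.997, ALOX5 1.85, CXADR 1.46, PPM1D 0.89 and FOSL1 1.26. It was negative for TRIM16 -1.74, TNS3 -1.59, AMIGO2 -1.67, AHNAK2 -1.34, WDR6 -1.83, SOX9 -1.10, ANO2 -1.70, BMP4 -1.72, CRYAB -1.93, TIMP3 -1.15, TGFBI -1.91, LTBP2 -0.72, MYBBP1A -1.004, CAV1 -2.23, MN1 -1.94, MICAL2 -1.92, ASCC1 -1.74, PLAC8 -1.43, HAPLN1 -1.53, DDIT4 -1.53, TGM2 -1.90, SCG5 -0.88, NAT10 -1.27, LAMB3 -1.35 and COL1A1 -0.97.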

How the results depend on the processing

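The fits without the Ad-GFP 26 h array were chosen after that array was seen to stand apart. Of 3917 alternative values for the 170 results on named genes, 3777 kept direction and side of the threshold, 104 lost the call, 27 gained it and 9 turned. The HIC1 transcript level kept its direction throughout (log2 5.91 to 10.14). Without the hour as a block pairing the viruses 2668 genes differed over all hours. Values on arrays are limited by signal near background, as for genes under the filter. With fewer or more probe sets tested, counts move by construction. For the rest the cause was not tested.

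Of 11111 probe sets tested singly, 4533 passed over all hours, 3662 late, 1322 for the Ad-GFP trend and 2992 for the Ad-HIC1 trend. The fits without _s_at and _x_at probe sets tested 4062 genes. Without _s_at and _x_at probe sets the counts were 1767 over all hours, 314 for the interaction, 236 early, 996 in the middle, 1428 late, 460 for the Ad-GFP trend and 1103 for the Ad-HIC1 trend. No filter gave 379 for the interaction, median centring 223 early, array weights 2685 in the middle, and Ad-GFP arrays alone 495. Without 8, 16 and 26 h the counts were 63 (interaction), 1034 (middle), 1376 (late), 51 (Ad-GFP trend) and 879 (Ad-HIC1 trend), and without the Ad-GFP 26 h array 345 (interaction) and 481 (Ad-GFP trend). Leaving out 1 hour at a time gave 237 to 625 for the interaction, 123 to 537 early, 807 to 1939 in the middle, 375 to 1090 for the Ad-GFP trend and 1088 to 1938 for the Ad-HIC1 trend. Of the lists 2 passed with camera at a preset correlation and 0 at an estimated one.

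Only values near 0 turned direction, apart from lists without the filter. They were KRT18 with median centring (0.0246), CD48 with quantile normalization (0.0479), median centring (0.0578), without 8, 16 and 26 h (0.121) and without the Ad-GFP 26 h array (0.0225), and, with 1 hour left out, CDKN1C (-0.0153 to 0.125) and CD48 (-0.107 to 0.0301). Without the filter the lists for p53 (0.00716), NF-kB (0.149), heat shock (0.116) and immediate early genes (0.0622) turned, and with quantile normalization those for the BCL2 family (-0.00543) and corepressors (-0.0294). With 1 hour left out the p53 list ranged from -0.0301 to 0.0146, the BCL2 family from -0.0102 to 0.0164 and corepressors from -0.00625 to 0.0166.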

Other observations

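The array whose title calls it a control and whose description names Ad-HIC1 at 8 h was placed in no group. Its HIC1 intensity was 1.98, against 0.834 to 7.68 on the Ad-GFP arrays and 1589 to 5903 on the Ad-HIC1 arrays. That value argues against the description, while the kind of control stays open. PTN read 45.6, ID4 82.9, MMP12 42.1, SNAPC1 1002, ACKR3 211, LIF 242 and CCND1 354 on it. On the Ad-HIC1 8 h array these genes read 1051, 395.5, 55.5, 543, 105.9, 101.5 and 254.9. Across probe sets the correlation of the unplaced array with the others ranged from 0.957 (Ad-HIC1 at 26 h) to 0.977 (Ad-GFP at 22 h).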
